A study of Xenopus tropicalis with 3 samples.

How the data were processed

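The series holds 3 libraries from the frog Xenopus tropicalis, 1 in each of 3 groups. Chromatin from 400 embryos at Nieuwkoop-Faber stage 12, late in gastrulation, was fixed in 1% formaldehyde, sheared by sonication and precipitated with 2 µl of an antibody against TBP, the TATA-binding protein, per the labels' protocols. TSS-seq, which sequences from the 5' ends of capped transcripts, was made from oocytes and from embryos labelled stage 12 in the title and stages 10 to 12 in the characteristics. Each TSS-seq library started from 50 µg of total RNA, which was dephosphorylated, ligated to an RNA oligonucleotide, copied from random primers and amplified by 20 cycles of PCR, per the labels' protocols.

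All coordinates are those of the xenTro2 (JGI4.1) assembly, per the deposited readme. The ChIP reads were filtered by the authors for unique mapping and are described as 35 bp reads, per the deposited readme; the deposited intervals are 32 bp long. TBP peaks were called with MACS at a p-value threshold of 1e-07, per the deposited readme, and each was deposited as a single position with the count of reads in the peak as the authors gave it. That count was used only to describe, rank and filter peaks within the list. No control library is named in the sources used here, and the aligner is not given in the sources used here. The TSS-seq reads were deposited as start positions of reads that mapped uniquely. Called start sites (TSS) were deposited with a count of overlapping TSS-seq reads; per the deposited readme they are positions with at least 20 overlapping reads, kept by the authors only where they overlapped a TBP peak or an H3K4me3 peak from an earlier study. Part of the overlap between TSS and TBP peaks is therefore built into the list. The H3K4me3 peaks and the extents of the TBP peaks were not used here. The files do not say whether positions count from 0 or from 1, so positions are printed as deposited and can be off by 1 bp.

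The TSS-seq reads of both stages lie in 1 deposited file with no column that tells the libraries apart, so every TSS-seq value is a pooled value and the comparison of oocytes with stages 10 to 12 was not made. No genome sequence of xenTro2 was used here, so the planned description of core promoter sequence was not made. The gene table at hand belongs to another assembly, so the gene lists fixed beforehand were not used and regions are named by scaffold and position. The rule for named regions, fixed before the data were examined, took the 5 TSS with most tags, the 5 peaks with most reads in the authors' count and the 5 such peaks with no TSS within 1000 bp. The main tests and most alternatives were also fixed before the data were examined.

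The pooled TSS-seq file gave 2505420 reads on 492689 positions by strand, after 2 reads at positions below 1 were left out. The ChIP file gave 8342397 reads. It consists of 2 blocks of lines written in different ways, with 3592317 reads in the first, where each position and strand occurs once, and 4750080 reads in the second, where repeats are kept. A read is called unique here when it was kept once per position and strand over both blocks, which left 7020267 reads. The fragment length from the cross-correlation of the strands was 154 bp in each block, and each read was moved by 77 bp towards the middle of its fragment.

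A peak and a TSS were called shared when the peak position lay within 200 bp of the TSS. Shares have exact Clopper-Pearson 95% intervals and were set against 1000 placements of the TSS at random positions on the same scaffolds (one-sided resampling p, at least 0.000999). The TBP profile around TSS was smoothed over 21 bp, and the interval of its mode comes from 1000 bootstrap resamples of the TSS. Enrichment is the ratio of mean reads within 200 bp of the TSS to mean reads at 3 to 5 kb on both sides, with the same bootstrap. TSS-seq tags were counted on the TSS strand within 50 bp. A TSS with at least 20 tags was called sharp when at least 50% of them lay within 2 bp of the most used position, and broad otherwise. Spearman's rho and differences of medians were tested with 100000 permutations, differences of the mode and of the interquartile range of peak distances with 10000 permutations, and shares of TSS with a peak, by divergence and by shape, with Fisher's exact test, all two-sided. Tests within quartiles of tags were adjusted over the 4 quartiles by the Benjamini-Hochberg method. Alternatives changed the distances, windows, tag minimum, definition of sharp TSS, handling of repeated reads and choice of TSS; those added after the data were seen used all TSS-seq clusters at least 20 reads deep, each block of ChIP reads alone, and other sets and placements. With 1 library per group there is no replicate error: TSS are not replicates, and every p describes these libraries only. Intervals cover counting error only, since PCR reads without molecular identifiers are not independent molecules.

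The scripts ran in Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9. They were tested on simulated data with 2000 sites: a TBP position of -40 bp was recovered as -40 bp, an enrichment of 8.10 as 8.13, and a share of 39.25% sharp sites as 39.25%. Every simulated site lay far from the 50% cut between sharp and broad, so the recovered share does not test calls near that cut. In the data, 276 TSS had 45 to 50% of their tags within 2 bp and 287 had 50 to 55%. In 100 shuffles of the simulated classes, 0 gave p under 0.05 for the difference of median reads, against 6 when tied counts were broken at random, so that test is strict on tied counts.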

Results

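TBP, the DNA-binding subunit of the general transcription factor TFIID, was mapped by ChIP-seq in Xenopus tropicalis embryos at stage 12, and the 5' ends of capped transcripts were mapped by TSS-seq in oocytes and in embryos of stages 10 to 12. The pairing of the assays asks where TBP lies at core promoters and how its binding relates to where and how sharply transcription starts. There was 1 library per group and the TSS-seq reads of both stages were pooled in the data, so no comparison between stages was made and no value has a replicate error. The ChIP library held 8342397 reads and 7675 peaks on 1594 scaffolds, with a median of 46 reads per peak (range 12 to 2267). The pooled TSS-seq data held 2505420 reads and 4183 called start sites (TSS) on 985 scaffolds, with a median of 49 reads per TSS (range 20 to 24350). Of these TSS, 2073 lay on the plus strand and 2110 on the minus strand, and 99.6% stood at the most used TSS-seq position within 50 bp. All positions are in xenTro2, whose gene annotation was not used here.

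Most TSS had a TBP peak close by, but most TBP peaks had no TSS close by. Of the 4183 TSS, 2541 (60.7%, 95% interval 59.2 to 62.2%) had a TBP peak within 200 bp. Of the 7675 peaks, 2382 (31.04%, 30 to 32.1%) had a TSS within 200 bp. The share of TSS with a peak was 53.3% in the quartile with fewest TSS-seq tags and 71.1% in the quartile with most, and their median unique ChIP reads within 200 bp were 24 and 45. The share of peaks with a TSS was 14.3% in the quartile with fewest reads per peak and 44.6% in the quartile with most. Random placement of the TSS on the same scaffolds gave a mean of 0.580% of TSS with a peak (highest 0.932%) and 0.290% of peaks with a TSS (highest 0.495%), so both observed shares lay above all 1000 placements (one-sided permutation of TSS positions, p = 0.000999, the smallest they can give). The TSS list was itself filtered for a TBP or H3K4me3 peak, and in all 10918 TSS-seq clusters at least 20 reads deep, taken without that filter, 26.4% had a peak against 0.414% at random. Of the peaks, 27.5% had such a cluster within 200 bp, fewer than had a listed TSS. The clusters were called here from overlapping reads, so they differ from the list in more than the filter. Within 50 bp the shares in the list were 22.3% of TSS and 12.1% of peaks.

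**Figure D1:**
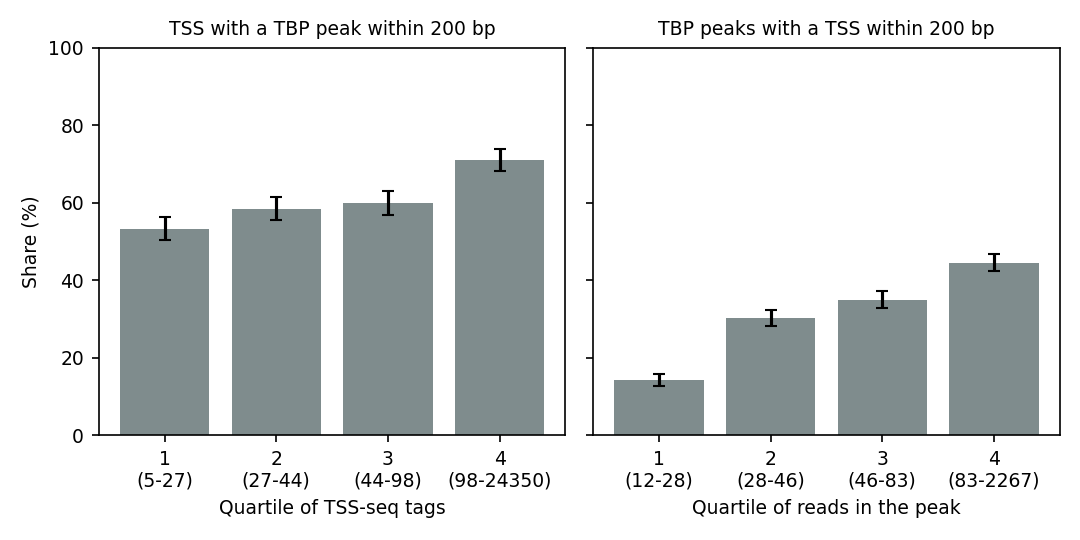
Share of TSS with a TBP peak within 200 bp by quartile of TSS-seq tags (left, range of tags in parentheses) and share of TBP peaks with a TSS within 200 bp by quartile of reads in the peak (right), in percent with exact 95% intervals. The shares go from 53.3% to 71.1% on the left and from 14.3% to 44.6% on the right.

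The TSS with most tags differed in how sharply they started and in the TBP reads beside them. The TSS on scaffold 29 at position 4245366 (plus strand) had 24350 tags, of which 99.7% lay within 2 bp, and its nearest TBP peak lay 217 bp downstream. The TSS on scaffold 91 at position 1742416 (minus strand) had 17687 tags within 50 bp, of which only 25.4% lay within 2 bp, and a TBP peak at -66 bp. The TSS on scaffold 26 at position 2163856 (minus strand) had 16483 tags, 90.5% of them within 2 bp, and a peak at -68 bp. On scaffold 1166 at position 139227 (minus strand), 47.7% of 16019 tags lay within 2 bp and the peak stood at -77 bp. On scaffold 109 at position 1384748 (minus strand), 94.7% of 8626 tags lay within 2 bp and the peak stood at -98 bp. Unique ChIP reads within 200 bp of these 5 TSS numbered 47, 98, 100, 181 and 130 in the order given.

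**Figure D2:**
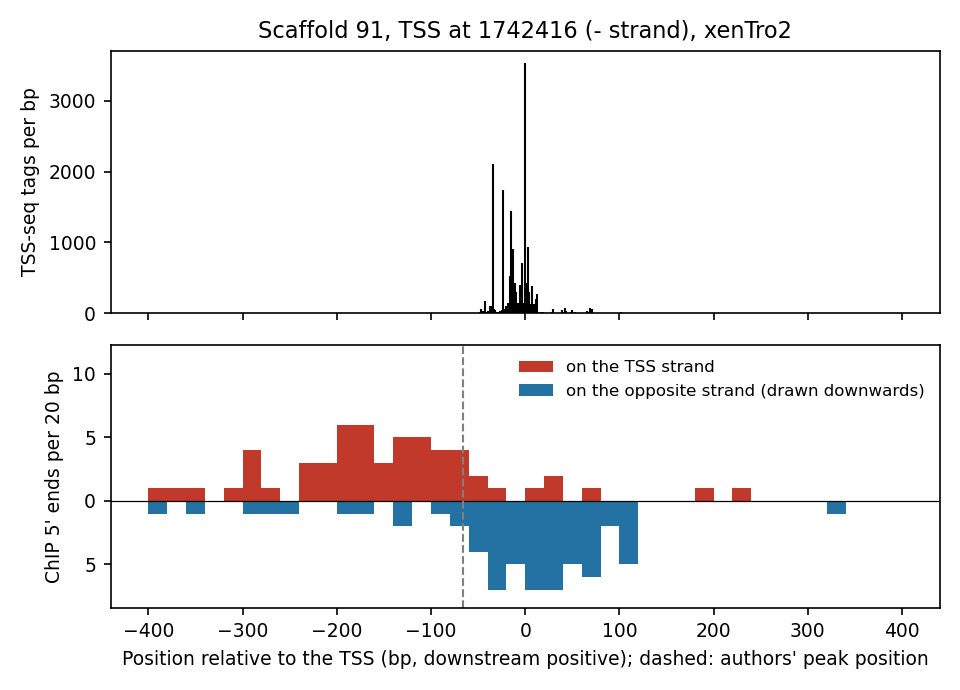
Start region on scaffold 91 at position 1742416 (minus strand) in xenTro2, oriented so that transcription runs to the right. The upper panel gives TSS-seq tags per bp, which spread over many positions, and the lower panel gives 5' ends of unique ChIP reads per 20 bp on each strand, with the authors' peak at -66 bp (dashed line) between the strands' reads.

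TBP peaks without a TSS were common, less so among the strongest peaks. Of the 1919 peaks in the quartile with most reads, 984 (51.3%, 49.0 to 53.5%) had no TSS within 1000 bp, against 71.1% (69.9 to 72.3%) of the other peaks, and 394 (20.5%, 18.7 to 22.4%) also had no tag on either strand within 200 bp. The 5 peaks with most reads were of both kinds. The peak with most reads, on scaffold 18215 at position 662 (2267 reads), had 1739 TSS-seq tags within 200 bp and a TSS at 149 bp; that scaffold reaches only to position 3332. The peak on scaffold 398 at position 765897 (1671 reads) had 0 tags within 200 bp and its nearest TSS 95377 bp away. The peak on scaffold 14923 at position 1936 (1279 reads) had 1 tag and no TSS on its scaffold, which reaches only to position 5851, and the peak on scaffold 165 at position 1269530 (1271 reads) had 0 tags and its nearest TSS at 101090 bp. The peak on scaffold 43 at position 2619976 (1227 reads) had 184 tags and a TSS at 375 bp. Unique ChIP reads within 200 bp of these 5 peaks numbered 627, 322, 277, 235 and 576 in the order given. The next strongest peaks chosen for having no TSS within 1000 bp lay on scaffold 75 at position 39441 (1033 reads, 1 tag) and on scaffold 22 at position 2223263 (870 reads, 0 tags). Over all strengths, 5076 peaks had no TSS within 1000 bp, with a median of 40 reads against 61 in peaks with a TSS. Of these, 2202 (43.4%, 42.0 to 44.8%) had no tag on either strand within 200 bp and 5.14% had at least 20 tags, whereas 90.8% of random positions on the same scaffolds had no tag. A count of 0 tags means that none was seen at this depth.

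TBP lay upstream of the start site. The profile of ChIP reads over the 4183 TSS was highest at -65 bp (95% bootstrap interval -69 to -64), with modes of -65 bp at plus strand TSS and -64 bp at minus strand TSS. Before reads were moved by the fragment shift, the modes of the strands were -142 and 12 bp. Over the 2541 TSS with a peak, the peak position had a median of -62 bp (quartiles -96 and -32) and 90.2% of peaks lay upstream. From -100 to -20 bp lay 61.0% of them (59.1 to 62.9%), and from -35 to -25 bp, where a TATA box usually lies, 8.34% (7.30 to 9.49%). The second range is much narrower than the first, so the shares cannot be compared as they stand. The peak distances come from fragments of 154 bp.

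**Figure D3:**
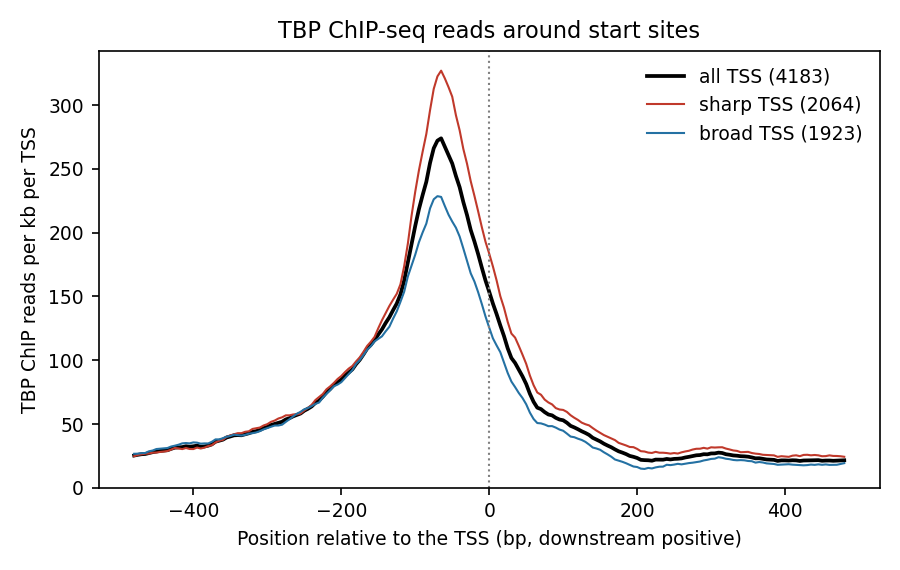
Mean unique TBP ChIP reads per kb against position relative to the TSS in bp, for all 4183 TSS, 2064 sharp TSS and 1923 broad TSS. Each curve is highest upstream of the TSS, at -65 bp for all and for sharp TSS and at -68 bp for broad TSS. At -65 bp the curves stand at 327 reads per kb for sharp and 228 for broad TSS, heights that were not tested.

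ChIP reads were concentrated at TSS over their surroundings, also at listed TSS without a called peak but hardly at unlisted clusters without one. No control library was used, so this enrichment does not tell TBP binding from an excess of reads that arises without the antibody. Within 200 bp of 4014 TSS whose flanks could be measured, the mean was 116 unique reads per kb against 8.27 reads per kb at 3 to 5 kb, a ratio of 14.1 (13.4 to 14.8). At TSS with a peak within 200 bp the ratio was 22.5 (21.6 to 23.4, n = 2436), and at TSS with no peak within 1000 bp it was 3.2 (2.90 to 3.51, n = 1186). The list had been filtered for a TBP or H3K4me3 peak, and at unlisted TSS-seq clusters with no peak within 1000 bp the ratio was 1.06 (1.01 to 1.12, n = 6139). Median reads within 200 bp were 48 at TSS with a peak and 12 at TSS without. The peaks were called from these same reads, so higher values at TSS with a peak were built in. Across the 4183 TSS, ChIP reads and TSS-seq tags rose together weakly (Spearman's rho = 0.214, two-sided permutation p = 1e-05, the smallest the permutations can give), a relation across TSS, which are not independent replicates. The tags pooled oocytes with embryos, whereas the ChIP reads came from embryos only. The ratio was 7.93 in a window of 500 bp and 7.84 over all unfiltered clusters.

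Initiation ranged from a single position to a wide stretch of positions, with no gap between classes. Tags of oocytes and embryos were pooled, so a TSS that used different positions in each could be called broad. Of 3987 TSS with at least 20 tags, 2064 (51.8%, 50.2 to 53.3%) were sharp. The share of tags within 2 bp of the most used position had a median of 50.0% and quartiles of 34.8 and 75%, and the width that held the tags from the 10th to the 90th percentile had a median of 31 bp and quartiles of 7 and 45 bp. Tags at 400 TSS lay at least 95% within 2 bp. The share of sharp TSS follows from the definition: it was 28.5% when the 10th to 90th percentiles had to lie within 10 bp. In the unfiltered clusters it was 71.5%.

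**Figure D4:**
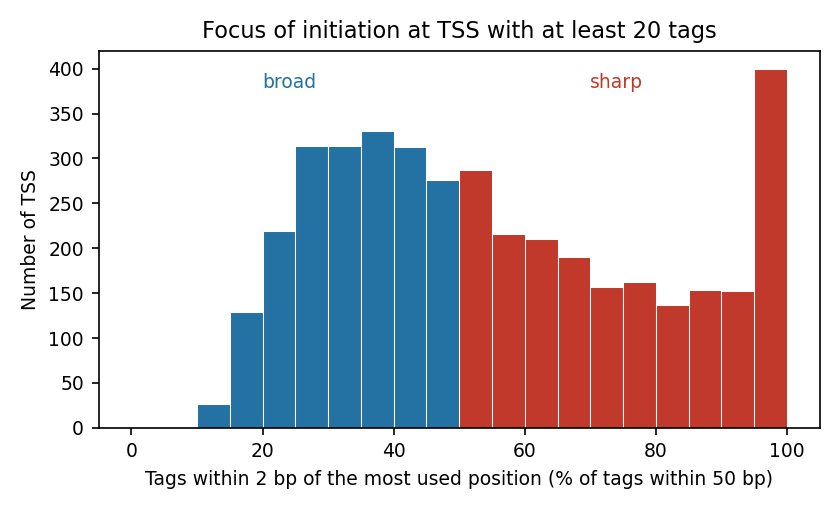
Number of TSS (3987 with at least 20 tags) by the share of tags within 2 bp of the most used position, in percent of tags within 50 bp and in steps of 5. Broad TSS (under 50%) are blue and sharp TSS red; 400 TSS stand in the last step, and no gap parts the classes at 50%.

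In the list, TBP reads were higher at sharp than at broad TSS among the TSS with most tags, and did not differ by the test elsewhere. The list had been filtered for a TBP or H3K4me3 peak, and the quartiles of tags were compared in it only. The difference in the share with a TBP peak changed with the definitions. In the quartile with most tags, the median was 57 unique reads at 590 sharp TSS and 36 at 407 broad TSS, a difference of 21 (two-sided permutation test, adjusted p = 4e-05 over 4 quartiles). In the other quartiles the differences, from fewest to most tags, were -0.5, -2 and 0 reads (permutation test, adjusted p = 1 in each). The difference in the highest quartile exceeded that in the others by 22 reads (bootstrap interval 14.5 to 31). That contrast was not fixed beforehand and sets the only quartile that passed against the rest, so it gives no separate support. The highest quartile was split at its median after the result was seen, and sharp TSS had more reads than broad TSS in each part. This split retests the same TSS without adjustment, so it gives no separate support either. The medians were 44 against 33 reads from 103 to 193 tags (p = 0.0026) and 79 against 42 reads from 194 tags up (p = 1e-05), both by two-sided permutation test. Sharp and broad TSS had median tags of 137 and 135 in the lower part and 394 and 322.5 in the upper part, so the upper part was not matched for tags. The tags that set the quartiles and the shape pooled oocytes with embryos, whereas the ChIP reads came from embryos only. A TBP peak lay within 200 bp of 73.2% (69.5 to 76.8%) of sharp and 70.02% (65.3 to 74.4%) of broad TSS in the quartile with most tags (Fisher's exact test, two-sided p = 0.283), and of 59.9% (57.7 to 62.0%) and 62.4% (60.1 to 64.5%) over all (exact p = 0.111). With sharp defined by a width of 10 bp the share was lower at sharp TSS (57.1%, 54.2 to 59.99%, against 62.7%, 60.9 to 64.4%, exact p = 0.00120), and in the unfiltered clusters it was 16.9% at sharp and 50.3% at broad ones (exact p = 1.32e-263). The mean profile was higher at sharp TSS, with 327 against 228 unique reads per kb at -65 bp, a difference of means that was not tested. Over all TSS the median reads within 200 bp were 31 at sharp and 29 at broad TSS, a difference of 2 that did not pass the test (two-sided permutation p = 0.166, a test that tied counts make strict, or p = 0.104 with ties broken at random). That overall difference was 10 among TSS with at least 50 tags (permutation p = 3e-05), while over all unfiltered clusters it turned to -20 (3 against 23 reads, p = 1e-05).

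The mode of TBP was not found to differ between sharp and broad TSS, and whether its spread differed changed with the definitions. The modes were -65 bp at sharp and -68 bp at broad TSS, a difference of 3 bp (two-sided permutation p = 0.359). The distances from peak to TSS had interquartile ranges of 61 bp at sharp and 66 bp at broad TSS, a difference of -5 bp (permutation p = 0.0678). With every ChIP read counted, the difference of modes was 6 bp (permutation p = 0.0314). The narrower spread at sharp TSS passed its permutation test where sharp was defined by a width of 10 bp (-14.5 bp, 51 against 65.5 bp) or tags were counted within 100 bp (-11 bp), with p = 1e-04 in each, the smallest the permutations can give, and under 3 other settings.

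Some TSS formed divergent pairs, and whether their TSS had a TBP peak less often than others changed with the gap, the strand and the filter on the list. A TSS on the opposite strand lay 0 to 1000 bp upstream of 396 of 4183 TSS (9.47%, 8.60 to 10.4%), against 0.355% with TSS at random. The distance between the members of a pair had a median of 268 bp (quartiles 152 and 395). Of the divergent TSS, 214 (54.0%, 49.0 to 59.0%) had a TBP peak within 200 bp, and of the others 2327 of 3787 (61.4%, 59.9 to 63.0%), a difference that passed Fisher's exact test (two-sided p = 0.00487). That test treats the members of a pair as independent, although a single peak can lie within 200 bp of both. Taken by strand, so that the members of a pair fell apart, the difference passed for plus strand TSS (50.3 against 62.6%, exact p = 0.000869) and not for minus strand TSS (57.7 against 60.3%, exact p = 0.496). In the list, which had been filtered for a TBP or H3K4me3 peak, the difference rested on the 57 TSS whose partner lay over 500 to 1000 bp upstream, a group set apart after the result was seen: 16 of them (28.1%, 16.97 to 41.5%) had a peak (exact p = 6.58e-07), 5 of 27 on the plus strand (exact p = 6.38e-06) and 11 of 30 on the minus strand (exact p = 0.0133), while 198 of the 339 with a closer partner had one (58.4%, 53.0 to 63.7%, exact p = 0.270 against the same 3787 TSS). The direction turned in the unfiltered clusters, where 45.1% of divergent and 25.6% of other clusters had a peak (exact p = 2.14e-18). By gap, 51.4% of the 370 unfiltered clusters with a partner up to 500 bp upstream had a peak (exact p = 3.74e-25), and 14 of the 82 with a wider gap (17.1%, 9.66 to 27.0%), which did not pass the test (exact p = 0.0973).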

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

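The tests of the ChIP blocks, and that of the distance from unlisted TSS-seq clusters to TBP peaks, were chosen after the result was seen; the test of their place downstream of listed TSS was chosen before it.

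Much of the TSS-seq signal lay outside the TSS list, on which the main comparisons rest. Of 10918 clusters at least 20 reads deep, 4032 held 24.3% of all TSS-seq reads and a listed TSS, and the other 6886 held 46.7% of the reads. The 10 largest of these held 16.9%, led by scaffold 143 at position 1697998 on the minus strand (114810 tags, 4.58% of all reads) and scaffold 59 at position 2511323 on the plus strand (76669 tags), each with 1 unique ChIP read within 200 bp; they were picked after their values were seen. The unlisted clusters were more often sharp (83.5 against 50.9%) and had a TBP peak within 200 bp in 5.42% of cases against 62.3%, a contrast partly set by how the list was made.

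Start sites just outside the reach of a TBP peak cannot be the source of most of them, since the nearest peak lay at 200 to 1000 bp from 86 unlisted clusters (1.25%, 1.00 to 1.54%). Unlisted clusters with no peak within 1000 bp had 1.06 times the ChIP reads of their flanks (1.01 to 1.12), against 3.2 (2.90 to 3.51) at listed TSS with no peak within 1000 bp. Capped or broken 5' ends inside the transcripts of listed TSS would lie downstream of those. Within 20 kb downstream of a listed TSS on the same strand lay 14.7% of unlisted clusters, more than the 7.73% upstream. Such ends within 20 kb are therefore not the source of most unlisted clusters. Ends farther along a transcript or on another scaffold were not counted, so the test does not reach them. Transcripts stored in the oocyte remain a possible explanation that was not tested, because the reads of the stages are pooled. Reads from repeated sequence, from uncapped transcripts or multiplied by PCR were not tested either.

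The 2 blocks of ChIP reads shared many positions outside TBP peaks, an overlap that was not itself compared in the report. More than 2 kb from any peak, 19.7% of the positions in the first block occurred in the second, 632452 positions where chance gives 4085. Independent libraries that share only enriched sites are hard to reconcile with this excess of 155 times. The number of molecules estimated from the overlap of the blocks was 1.08 times that estimated from repeats within the second block, so the blocks may be the same library sequenced again. On that hypothesis the blocks are technical repeats and say nothing of variation between embryos; no biological explanation was tested.

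Tags antisense to a TSS, which enter neither its tag count nor its shape, were common upstream of it. Of 3142 TSS with no other TSS within 1000 bp and with measurable flanks, 28.1% (26.5 to 29.7%) had a tag on the opposite strand within 500 bp upstream, against 8.24% (7.30 to 9.26%) at 4500 to 5000 bp upstream and 21.3% (19.8 to 22.7%) within 500 bp downstream.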

How the results depend on the processing

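The unfiltered TSS-seq clusters, the single blocks of ChIP reads, the shifted placements and the sets without dense windows or without the 10 TSS with most tags, the breaking of ties and the TSS of 1 strand were chosen after the data were seen. Under settings chosen beforehand 40 values kept their direction and side of the threshold, 5 moved, 8 newly passed a test and 1 no longer passed. Under the added ones 27 kept them, 2 moved, 2 newly passed, 1 no longer passed and 2 reversed. Both overlaps stayed above all random placements at every distance and in every set of peaks and TSS tried, from 12.1 to 39.7% of peaks and 22.3 to 70.4% of TSS. The TBP position stayed between -68 and -64 bp, the last at minus strand TSS. Enrichment lay between 7.84 and 18.7 and rho between 0.178 and 0.226. The share of sharp TSS moved to 53.7% with at least 50 tags, 28.5% by width, 41.9% with tags within 100 bp, 55.0% with each TSS thinned to 20 tags and 71.5% in unfiltered clusters. The difference of reads at sharp and broad TSS passed its test at 5 in a 500 bp window, at 10 with at least 50 tags and at 4 by width, and reversed to -20 in unfiltered clusters. The difference of modes passed at 6 bp with all ChIP reads and at 5 bp in the first block. The difference of interquartile ranges passed at -14.5 bp by width, -11 bp with tags within 100 bp, -6 bp with no other TSS within 1000 bp, -5.5 bp with at least 10 tags and -6 bp in unfiltered clusters. The share of divergent TSS moved to 8.10% within 500 bp and 4.14% in unfiltered clusters; the difference in their peak share was -2.55 points within 500 bp and -2.58 points at minus strand TSS, where it did not pass, and reversed to 19.5 points in unfiltered clusters. Unlisted clusters, mostly sharp and without a TBP peak, enter the unfiltered set. Other causes were not tested. No paired analysis was possible because each group has 1 library. The settings chosen beforehand for oocytes against stages 10 to 12 and for core promoter sequence were not run. Depth limits the shape of TSS near 20 tags and the absence of tags at peaks.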

Other observations

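The check of unique mapping at clustered TBP peaks, and the choice of the downstream ChIP reads, came after the result was seen; the other tests of clustered peaks were chosen before.

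A small part of the TBP peaks without a TSS, 211 of 5076, was gathered in a few regions. In 17 windows of 100 kb there were 10 or more peaks, up to 20 in a window, where 100 random placements of the peaks gave at most 7. They held 225 peaks on 13 scaffolds, of which 93.8% had no TSS within 1000 bp, against 65.3% of the other peaks. Scaffold 75 had 16 peaks from position 1 to 100000 and 17 from 100001 to 200000, none with a TSS within 1000 bp, and scaffolds 1099 and 7921 had 20 each in their first 100 kb. The clustered peaks without a TSS were strong, with a median of 96 reads in the authors' count against 39 in other peaks without a TSS, and 79.6% of them had no TSS-seq tag within 200 bp against 41.8%.

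The median enrichment of these peaks over reads outside peaks was 32.7 in the first block of reads and 35.4 in the second. A pile-up in only 1 block is therefore unlikely. A pile-up shared by the blocks, which may be the same library sequenced again, stays open. Sequence where TSS-seq reads cannot map uniquely stays open: these peaks had 2.24 times as many unique ChIP positions within 200 bp as other peaks, but they were called from such reads. Extra copies of the sequence, held once in the assembly, stay open too: ChIP reads more than 1 kb from peaks were 1.26 times as dense as in other windows, but the interval of that ratio ran from 0.867 to 2.56. RNA polymerase III also uses TBP and makes transcripts without the usual cap, but no biological explanation was tested, because gene positions in this assembly were not used.

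Downstream of the TSS, ChIP reads rose again after their fall. At 3263 TSS with no other TSS within 1000 bp, reads were 21.2 per kb at 280 to 320 bp downstream and 15.8 per kb at 200 to 240 bp, a ratio of 1.35 (1.24 to 1.47). Upstream, the same distances had 40.04 and 66.0 reads per kb.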
